A study of Mus musculus with 6 samples.

How the data were processed

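Total RNA of the substantia nigra was extracted with Trizol and made into strand-specific TruSeq libraries, per the labels' protocols. The deposited values are raw counts per Ensembl gene, with 1 file per library and 55335 genes in each. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.5.3a, Cuffnorm and DESeq 1.16.1 were used and the build was mm10. Which tool counted the reads, the annotation release and the strand setting are not given in the sources used here. Gene names and positions came from the GENCODE annotation of the same build, which matched 55154 of the 55335 identifiers. Some near-identical copies had counts in a steady ratio over libraries, such as mt-Atp6 and Gm10925 with 1.06 to 1.07, and others varied more, such as Hspa1a and Hspa1b with 0.52 to 0.71. How reads that fit several places were counted is not given in the sources used here. Values of such copies and of overlapping genes are uncertain.

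The groups came from the sample titles, and 1 comparison was made. The 3 libraries titled WT are called control here, and the other 3 are titled shDNAJB1. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold change was its size divided by the square root of the F statistic, and intervals are 95% from the t distribution with the fit's degrees of freedom. CPM values are TMM-scaled, except those of Th, Slc6a3, Gad1, Xist and the markers of neighbouring nuclei, which are CPM of all counts. The library totals, 24541386 to 38468363 counts, put the counting error of Dnajb1 at 2.14% to 3.03% per library, while the biological coefficient of variation over genes was 24.1%. Counting errors cover counting only.

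Before the data were examined, 42 gene lists were fixed, and the 40 with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation called 0 lists, and fry was run as an alternative. Adjustment over a list alone used Benjamini-Hochberg among the tested members of that list, without correction over the 42 lists. Genes named in the text were Dnajb1, then, with no gene past the threshold, the 5 in each direction with the smallest unadjusted p, separate groups, a mean of at least 1 CPM and a symbol that is not a clone name. Up to 4 members of each list with the smallest unadjusted p could be named as well, together with members that a count of 5 or fewer consists of. Mbp, Mobp, Th, Slc6a3, Gad1 and the genes called by DESeq2 alone were named after their values were seen.

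The procedure was tested on data simulated from these libraries, with 10 sets of 18870 genes of which 200 changed. At 10 CPM or more, 67.8% of 2-fold and 98.8% of 4-fold changes were recovered, and 89 of 1259 calls were false. A halved Dnajb1 was called in 10 of the 10 sets. Genes were simulated independently of each other, and recovery may be lower where fewer than 200 genes change.

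Alternatives were DESeq2 size factors, upper-quartile scaling, no filter beyond 1 count, a stricter filter (1 CPM in 3 libraries and a mean of 5 CPM), leaving out each library, a replicate block, DESeq2 1.42.0, limma-voom and other thresholds. Added after seeing the data were the dopaminergic or GABAergic list mean as a covariate, limma-voom with sample weights, and leaving out control 1 with shDNAJB1 3. Pseudocount alternatives applied only to normalized values and were not needed for counts. Correlations of log2 CPM were 0.960 to 0.982 within groups and 0.962 to 0.978 between groups, and every pair of libraries differed beyond sampling noise. Figures were drawn with matplotlib 3.10.9.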

Results

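Bulk RNA sequencing measured transcript levels in the substantia nigra, the midbrain nucleus that holds dopaminergic neurons, of C57 mice. There were 3 control libraries, titled WT, and 3 libraries labelled shDNAJB1 for a short hairpin RNA against Dnajb1. Dnajb1 codes for an HSP40 co-chaperone that works with HSP70. The titles do not say whether the control mice received a hairpin. The series asked which transcripts change in this tissue after knockdown of Dnajb1. Total gene counts were 38468363, 28955111 and 30309652 in control 1, 2 and 3, and 24541386, 27054274 and 38056533 in shDNAJB1 1, 2 and 3. Counts above 0 were present for 33190 genes, and 18870 genes were tested. Nothing in the labels says that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

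The Dnajb1 transcript was not detectably lower in the libraries labelled shDNAJB1. Dnajb1 (ENSMUSG00000005483) lies on chromosome 8, positions 83608193 to 83612653 of mm10, on the plus strand, and its 3204 exonic bases overlap no exon of another annotated gene. Its level was 59.8, 47.2 and 51.9 CPM in control 1, 2 and 3, from 2180, 1364 and 1561 counts. It was 44.3, 52.4 and 52.5 CPM in shDNAJB1 1, 2 and 3, from 1092, 1460 and 2048 counts. The group means were 52.999 ± 6.37 CPM (SD, n = 3) and 49.7 ± 4.71 CPM (SD, n = 3). The log2 fold change was -0.09 (SE 0.13), with a 95% interval from -0.39 to 0.21 and an adjusted p = 0.909 by edgeR's quasi-likelihood test. That interval corresponds to 76.2% to 116% of the control level. A two-sided exact permutation test of the 6 libraries gave p = 0.6, where 0.1 is the smallest value that 3 against 3 can give. Without control 1 the log2 fold change was 0.011. Because no fall of the target was detected, the second group is called the libraries labelled shDNAJB1 throughout, and every direction refers to that label.

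**Figure D1:**
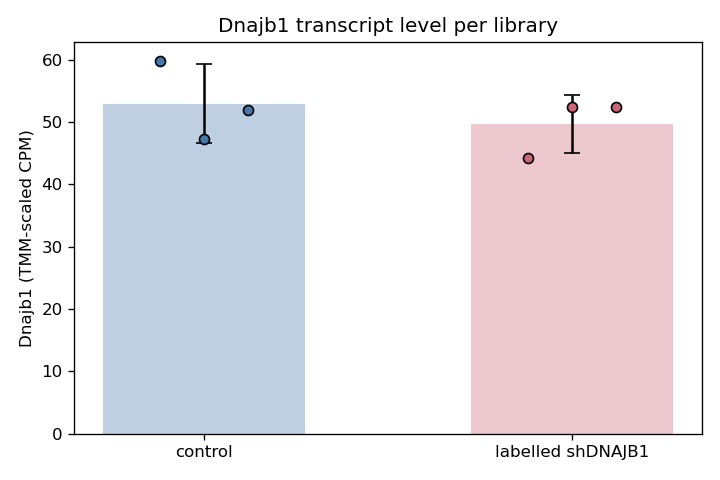
Dnajb1 level in TMM-scaled CPM on the vertical axis for the 3 control libraries and the 3 libraries labelled shDNAJB1. Points are libraries, bars are group means (52.999 and 49.7 CPM) and error bars are SD; the points of the groups overlap.

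No gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.765. At an unadjusted p under 0.05 there were 1202 genes, 573 higher and 629 lower, where 943.5 are expected on average by chance. Groupings of the libraries other than the real one gave 196 to 1717 such genes. The excess over 943.5 thus cannot be tied to the label. The groups did not overlap for 14.0% of the tested genes, and chance gives 10%. The limma-voom test also called 0 genes. DESeq2's Wald test called 24 genes, 7 higher and 17 lower in the libraries labelled shDNAJB1. Of these, 19 were among the genes that edgeR tested, and the groups of all 19 were separate in edgeR's CPM values. In data simulated from these libraries, the edgeR test recovered 39.3% of genes changed 2-fold and 76.7% of genes changed 4-fold among 18870 genes. Each simulated set held 200 changed genes, drawn independently, so recovery may be lower where fewer genes change.

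The genes with the smallest unadjusted p among those with separate groups did not pass by edgeR and are given as values, each with n = 3 libraries per group and an edgeR adjusted p = 0.765. Plin4, which codes for a lipid droplet coat protein, was at 26.3 ± 6.83 CPM (SD) in controls and 65.2 ± 5.89 CPM in the libraries labelled shDNAJB1, a log2 difference of 1.31 (SE 0.20). Icam1, an adhesion molecule of endothelium and leukocytes, was at 2.29 ± 0.24 and 5.84 ± 1.87 CPM. Pglyrp1, a peptidoglycan recognition protein, was at 4.68 ± 0.63 and 8.99 ± 0.65 CPM. Podxl, a sialomucin, was at 47.1 ± 4.34 and 71.2 ± 7.11 CPM, and Atxn7l2 was at 10.1 ± 1.75 and 17.6 ± 0.35 CPM. On the lower side, Rassf4 was at 53.8 ± 7.32 and 29.0 ± 3.98 CPM, a log2 difference of -0.89 (SE 0.15). Unc5b, a netrin receptor, was at 63.9 ± 5.08 and 39.0 ± 5.35 CPM. Grm3, a metabotropic glutamate receptor, was at 36.9 ± 2.31 and 23.1 ± 2.21 CPM. Pcyt1b, an enzyme of phosphatidylcholine synthesis, was at 64.8 ± 5.23 and 42.7 ± 2.32 CPM. Yy2, a zinc finger transcription factor gene, had 99, 74 and 62 counts in control 1, 2 and 3 and 0, 0 and 6 counts in shDNAJB1 1, 2 and 3. All 2867 exonic bases of Yy2 lie inside exons of Mbtps2 on the same strand, so its counts are uncertain. Exons of Icam1 overlap those of Gm47079 on the opposite strand by 511 bases, and those of Plin4 overlap Hdgfl2 by 17 bases. By DESeq2's Wald test Plin4, Icam1, Yy2, Rassf4, Grm3, Pcyt1b and Unc5b passed, with adjusted p = 4.1e-06 for Plin4 and 8.44e-07 for Yy2.

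Oligodendrocyte transcripts were lower in the libraries labelled shDNAJB1 across the list fixed for that cell type. All 13 measured members of the oligodendrocyte and myelin list had lower values, with a median log2 difference of -0.52 and a camera adjusted p = 2.42e-08. The call was lost with adjusted p = 0.853 with an estimated correlation, which was 0.849 between members. Over all genes 0 members passed, and adjusted over the list alone 5 passed. These were Myrf, the transcription factor of myelin gene expression (157 ± 3.26 and 109 ± 14.8 CPM), Ugt8a, an enzyme of galactolipid synthesis (167 ± 10.8 and 110 ± 19.0 CPM), Aspa, Opalin and Ermn. The most abundant members had smaller differences, -0.22 (SE 0.26) for Mbp and -0.15 (SE 0.24) for Mobp, which code for myelin proteins. The list mean was lowest in shDNAJB1 3, and leaving that library out moved the mean log2 difference from -0.48 to -0.31, with camera adjusted p = 2.54e-05. GABAergic markers were also lowest in shDNAJB1 3, with Gad1 at 57.5 CPM there and 250 to 887 CPM in the other 5 libraries.

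**Figure D2:**
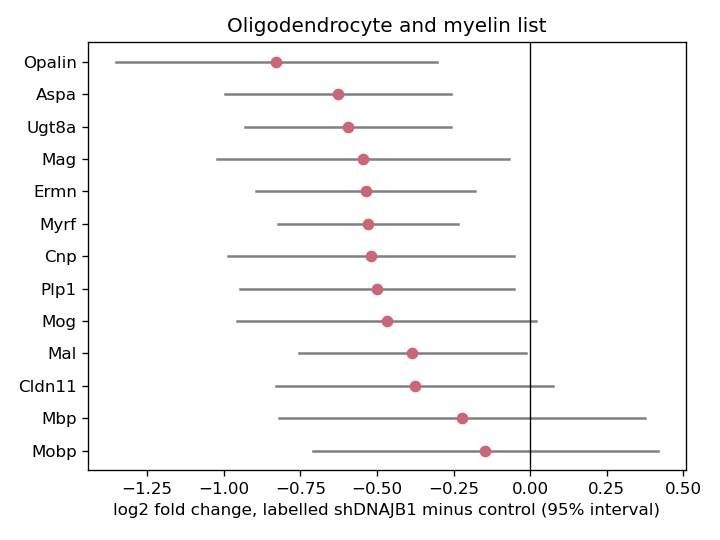
Log2 fold change of each of the 13 measured members of the oligodendrocyte and myelin list, libraries labelled shDNAJB1 minus control, on the horizontal axis. Points are edgeR estimates and lines are 95% intervals; all 13 estimates lie below 0 and the intervals of Mog, Cldn11, Mbp and Mobp include 0.

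Among the other glial and vascular lists, camera called the astrocyte list lower, with 9 of 12 members lower, a median of -0.23 and adjusted p = 0.0403. The call was lost with adjusted p = 0.853 with an estimated correlation. Slc1a2, the main astrocytic glutamate transporter, was at -0.38 (SE 0.15), and 0 members passed adjusted over the list alone. Leaving out control 1, control 2 or shDNAJB1 2 ended the astrocyte call, with adjusted p of 0.249, 0.147 and 0.256 and list means of -0.174, -0.135 and -0.133 against -0.212. Reactive astrocyte genes had 9 of 15 members higher, a median of 0.00, which ran from -0.05 without control 3 to 0.41 without control 2, and camera adjusted p = 0.392. Lcn2, a secreted protein of reactive astrocytes, was at 2.31 ± 1.76 and 9.90 ± 5.29 CPM, and 0 members passed. Homeostatic microglia markers were lower in 12 of 12 members (median -0.26, adjusted p = 0.0758), with medians from -0.88 without shDNAJB1 1 to 0.06 without control 2 on leaving out 1 library. Activated microglia and macrophage genes were lower in 9 of 16 (median -0.10, adjusted p = 0.467), with medians from -0.55 to 0.20 without the same libraries. Oligodendrocyte precursor markers were lower in 5 of 10 (median -0.01, adjusted p = 0.708). Endothelial markers were higher in 9 of 10 (median 0.16, adjusted p = 0.253), and mural cell and fibroblast markers in 10 of 15 (median 0.11, adjusted p = 0.597). These 2 medians ran from -0.09 and -0.04 without shDNAJB1 1 to 0.32 and 0.31 without shDNAJB1 3. Choroid plexus and ependyma markers were higher in 4 of 8 (median -0.03, adjusted p = 0.392). Blood cell markers were lower in 5 of 5 (median -0.58, adjusted p = 0.195), with medians from -0.94 without shDNAJB1 2 to -0.07 without control 1, and of these Hba-a1 and Hba-a2 are near-identical copies with uncertain counts.

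Chaperone lists showed no call. The cytosolic heat shock response without Dnajb1 was lower in 15 of 25 members, with a median of -0.04 and camera adjusted p = 0.482. Hspa4l, an HSP110 family member, was at 412 ± 34.5 and 306 ± 20.7 CPM, and Cryab, a small heat shock protein gene, was at 130 ± 7.87 and 103 ± 16.3 CPM, and neither passed. Other members of the DnaJ family were lower in 21 of 28 (median -0.11, adjusted p = 0.0548). The unfolded protein response of the endoplasmic reticulum was lower in 15 of 22 (median -0.04, adjusted p = 0.542), and proteasome subunits in 23 of 31 (median -0.07, adjusted p = 0.241). Adjusted over the list alone, 0 members of these lists passed.

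Neuronal lists varied between libraries of both groups. Th, the rate-limiting enzyme of dopamine synthesis, ranged from 99.4 to 417 CPM over the 6 libraries, and Slc6a3, the dopamine transporter gene, from 184 to 1076 CPM. Dopaminergic markers were lower in 12 of 20 members (median -0.02, adjusted p = 0.968), with medians from -0.24 without shDNAJB1 1 to 0.48 without control 2. GABAergic markers were lower in 6 of 10 (median -0.26, adjusted p = 0.0756), with medians from -1.24 without shDNAJB1 1 to 0.13 without shDNAJB1 3. Glutamatergic and forebrain markers were lower in 7 of 12 (median -0.19, adjusted p = 0.441), with medians from -0.32 without control 2 to 0.11 without control 1. Striatal medium spiny neuron markers were lower in 5 of 10 (median 0.02, adjusted p = 0.684). Thalamus and hypothalamus markers were lower in 8 of 11 (median -0.68, adjusted p = 0.0756), with medians from -0.86 without control 2 to -0.36 without control 1. Rora, at 108 ± 25.1 and 67.5 ± 6.31 CPM, was the only member to pass adjusted over the list alone, and it did not pass over all genes. Serotonergic and noradrenergic markers had 4 members, too few for camera, with a median of -0.78 that ran from -2.07 without shDNAJB1 2 to 0.24 without control 1. Synapse genes were lower in 18 of 24 (median -0.08, adjusted p = 0.164). Parkinson disease genes were lower in 10 of 20 (median -0.03, adjusted p = 0.482).

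**Figure D3:**
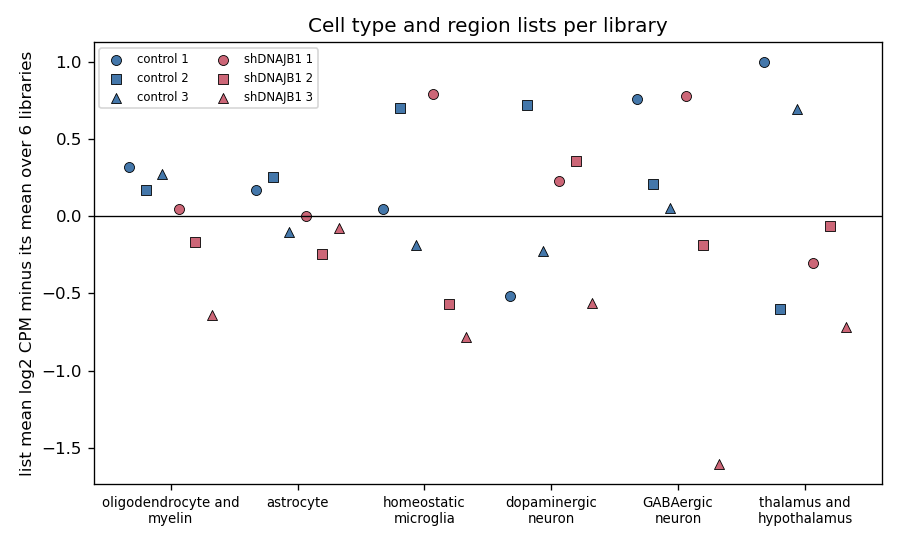
Mean log2 CPM of 6 fixed lists per library, minus the list's mean over the 6 libraries, on the vertical axis. Each point is a library, coloured by group and shaped by replicate number; the oligodendrocyte points of the groups do not overlap (lowest control 0.17, highest shDNAJB1 0.05), and the GABAergic point of shDNAJB1 3 is at -1.61.

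Immune, stress and ageing lists gave no call by camera, and over all genes 0 of their members passed. Passes adjusted over the list alone are not corrected for the 42 lists, so some can arise by chance. Inflammatory cytokines and NF-kB targets were higher in 9 of 13 members (median 0.06, adjusted p = 0.210), and Icam1 was the only member to pass adjusted over the list alone. Senescence and secretory phenotype genes were higher in 10 of 15 (median 0.05, adjusted p = 0.491), with Cdkn1a, a cyclin-dependent kinase inhibitor gene, at 10.7 ± 1.08 and 17.3 ± 2.20 CPM the only one to pass over the list alone. The p53 targets were higher in 9 of 18 (median 0.00, adjusted p = 0.760), and Cdkn1a again was the only one. Glucocorticoid targets were higher in 8 of 12 (median 0.12, adjusted p = 0.146), and Cdkn1a, Map3k6 and Lcn2 passed over the list alone. The mixed-direction test of fry, which asks only whether members change in either direction, called the p53 list (adjusted p = 0.00465) and the glucocorticoid list (adjusted p = 0.012), and its directional test called 0 lists. Immediate early genes were higher in 10 of 15 (median 0.12, adjusted p = 0.410), and Npas4, an activity-dependent transcription factor gene, at 4.27 ± 0.85 and 9.11 ± 1.77 CPM, passed over the list alone.

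Interferon response genes were lower in 14 of 23 members (median -0.04, adjusted p = 0.482), and complement genes in 10 of 15 (median -0.08, adjusted p = 0.590). MHC class I genes were higher in 12 of 14 (median 0.10, adjusted p = 0.392), and MHC class II genes in 3 of 7 (median -0.02, adjusted p = 0.853). The class I median ran from -0.08 without shDNAJB1 1 to 0.31 without shDNAJB1 3. Lymphocyte and infiltrating leukocyte markers were higher in 4 of 6 (median 0.17, adjusted p = 0.636). Proliferation genes were higher in 7 of 13 (median 0.08, adjusted p = 0.687), and circadian clock genes in 5 of 15 (median -0.06, adjusted p = 0.392). The 4 sex-linked genes tested, all Y-linked, had a median of 0.21, which ran from 0.05 without control 1 to 0.33 without control 3, and Xist was at most 0.37 CPM in every library, so all 6 libraries had a male pattern.

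Among metabolic and organelle lists, camera called autophagy and lysosome genes lower, with 22 of 28 members lower, a median of -0.13 and adjusted p = 0.024 (0.853 with an estimated correlation, which ended the call). Npc1, a lysosomal cholesterol transporter gene, was at 139 ± 4.69 and 104 ± 9.15 CPM. Antioxidant and NRF2 targets were called lower, with 16 of 21 members lower, a median of -0.15 and adjusted p = 0.024 (0.853 with an estimated correlation, which ended the call). Gclm, a subunit of the enzyme for glutathione synthesis, was at 114 ± 4.75 and 91.5 ± 3.89 CPM. Cholesterol synthesis genes were called lower, with 15 of 17 lower, a median of -0.16 and adjusted p = 0.0403 (0.853 with an estimated correlation, which ended the call). Ribosomal protein genes were called higher, with 33 of 37 higher, a median of 0.09 and adjusted p = 0.0403 (0.853 with an estimated correlation, which ended the call). In these 4 lists 0 members passed adjusted over the list alone, and the list means were -0.125, -0.135, -0.151 and 0.099. Leaving out single libraries also ended the calls. The autophagy call was lost without control 1, shDNAJB1 2 or shDNAJB1 3, with adjusted p of 0.320, 0.0754 and 0.124 and list means of -0.076, -0.097 and -0.077. The antioxidant call was lost without the same libraries, with 0.320, 0.107 and 0.109 and list means of -0.068, -0.094 and -0.105. The cholesterol call was lost without control 1 or shDNAJB1 1, with 0.432 and 0.809 and list means of -0.052 and -0.030. The ribosomal call was lost without control 2, control 3 or shDNAJB1 1, with 0.267, 0.455 and 0.990 and list means of 0.075, 0.068 and -0.002. It was also lost with no low-count filter, with 0.103, where the list mean was 0.094. Without both control 1 and shDNAJB1 3, left out after seeing the data, the autophagy, antioxidant, cholesterol and astrocyte calls were lost, with 0.701, 0.718, 0.0796 and 0.0796 and list means of -0.028, -0.038, -0.140 and -0.193. With the GABAergic list mean in the model, chosen after seeing the data, the autophagy, antioxidant and astrocyte calls were lost, with 0.270, 0.278 and 0.0527. Their list means were then -0.064, -0.080 and -0.197, against -0.125, -0.135 and -0.212 in the main test. The same model kept the other 3 calls, with list means of -0.253 against -0.151 for cholesterol synthesis, 0.192 against 0.099 for ribosomal proteins and -0.324 against -0.483 for oligodendrocytes.

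Nuclear-encoded oxidative phosphorylation genes were lower in 38 of 42 members (median -0.07, camera adjusted p = 0.0756), and mitochondrially encoded transcripts in 8 of 13 (median -0.02, adjusted p = 0.590). Ferroptosis and iron handling genes were lower in 11 of 18 (median -0.10, adjusted p = 0.467). Of the 36 lists that camera did not call, 27 had a median that changed sign when some single library was left out.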

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

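The alternatives with a covariate, with sample weights or without 2 libraries were chosen after seeing the data. The count of 0 genes was 24 in DESeq2's Wald test and 0 in the other 19 alternatives, of which the thresholds stricter than the main one could give only 0; the cause was not tested. Leaving out 1 library gave 0 genes each time. The Dnajb1 log2 fold change was 0.0191 in limma-voom with sample weights and -0.17 to 0.011 on leaving out 1 library, and the sign changed without control 1; its adjusted p ranged from 0.815 to 1.00 over 17 alternatives. Genes with an unadjusted p under 0.05 numbered 751 to 2514 on leaving out 1 library, 2870 with sample weights and 687 without control 1 and shDNAJB1 3. Lists called numbered 2 to 13 on leaving out 1 library, 0 in camera with an estimated correlation, 0 in fry and 3 without control 1 and shDNAJB1 3. The oligodendrocyte call was kept in 14 of 16 alternatives and lost in the estimated correlation and fry. All 14 used camera at the preset correlation of 0.01, against an estimated 0.849, so they do not test that setting. The ribosomal list mean was -0.00167 without shDNAJB1 1 and up to 0.168 on leaving out another library. The cause was not tested for these. The replicate block used numbers that do not pair the libraries (correlations of deviations 0.04, -0.02 and 0.08). It gave 0 genes, 1458 genes with an unadjusted p under 0.05, 8 lists and -0.09 for Dnajb1. With the block the cholesterol list had a camera adjusted p = 0.0716, which ended the call, and a list mean of -0.159 against -0.151. The ribosomal call was lost with no low-count filter (0.103) and the dopaminergic covariate (0.0672), with list means of 0.0937 and 0.0980 against 0.0991. For 97 named genes, 1611 of 1630 values kept direction and side of the threshold, and 19 passed in DESeq2. With 0 genes past the threshold in the main test, keeping the side meant staying uncalled. The set included every DESeq2 call that edgeR tested, so the 19 passes are in it by construction. Of list members it held up to 4 per list with an unadjusted p under 0.1, a limit set after sign changes were seen. These values therefore do not measure how robust the genes are. Among 89 other members, 29 changed sign at least once, in 66 of 1490 values. Depth limits low genes most.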

Other observations

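The tests of Dnajb1 read depth, label exchange and partial loss, of the oligodendrocyte list without 1 library, of Mbp with Mobp, of oligodendrocyte transcripts outside the list, of p53 and glucocorticoid activity and of the overlap of Yy2 were chosen after the results were seen. Among the 24 genes that DESeq2 called were 5 neuronal genes lower in the libraries labelled shDNAJB1, named after their values were seen. Kcna1, a potassium channel gene, had an edgeR log2 difference of -1.08 (SE 0.24). Scn8a, a sodium channel gene, was at -0.61 (SE 0.13), and Glra1, a glycine receptor subunit gene, at -1.80 (SE 0.41). Syt2 and Rph3a, genes of synaptic vesicle release, were at -1.10 (SE 0.30) and -0.75 (SE 0.15). By edgeR none of these 5 passed, with an adjusted p = 0.765 each.

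Single libraries held transcripts of nuclei near the substantia nigra. Pmch, a peptide gene of the lateral hypothalamus, was at 141 CPM in control 3 and at most 4.14 CPM elsewhere, and Hcrt, from the same region, was 108.9 times as high in control 3 as in the next library, which held few counts. Cartpt was at 353 CPM in shDNAJB1 2, and Ucn, made with it in the Edinger-Westphal nucleus, was 54.1 times as high there as in the next library. As hypotheses, both fit tissue of these regions in the dissections, which may add group differences that do not come from the label. In control 1, Tcf7l2 (153 CPM) and Prkcd (89.7 CPM) were highest, as were Gbx2 and Lhx9 (18.6 CPM, at most 5.87 CPM elsewhere). Synpo2 was 2.51 times the next library there, but Slc17a6 was 0.54 times the highest other library, shDNAJB1 3 (563 CPM). Tcf7l2 and Prkcd were lowest in shDNAJB1 3, so Slc17a6 did not follow them and its ratio cannot decide. Thalamic tissue in control 1 stays open.

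The Dnajb1 transcript was not detectably lower in the libraries labelled shDNAJB1. Too few reads for a halving is argued against by the lower limit of the interval, -0.39. An exchange of labels that hides a halving is argued against by the lowest library, at 84.9% of the median of the 6. The upper limit of the interval, 0.21, also argues against such an exchange. An exchange of labels with a smaller loss remains open. Hiding by differences in dissection remains open, since the dopaminergic list differed between groups by only 0.015 and that covariate, with -0.0839 for Dnajb1, could hardly move it, while the GABAergic covariate gave -0.130. A loss in part of the cells remains open, since the interval allows a loss of up to 23.8%, and the biological effect of the knockdown was not tested apart from it.

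For the lower oligodendrocyte list, dependence on shDNAJB1 3 alone is argued against by a mean of -0.31 without it. Length or GC bias is argued against by 10000 matched lists, with a middle median of -0.09 and a lowest of -0.28, against -0.52. Members of the matched lists were drawn independently, while the list's estimated correlation was 0.849. The list's percentile of 0 among them is therefore not a p-value. The 21 oligodendrocyte transcripts outside the fixed lists had a median of -0.50, 19 of them lower, which is consistent with a fall of these transcripts in general. Mbp and Mobp, picked after their smaller differences were seen, differed from the other 11 members by 0.32 (SE 0.18, exact permutation p = 0.1, the smallest possible), which decides nothing. Fewer oligodendrocytes or less white matter in the tissue cannot be told apart from a change within cells, since whole tissue was measured. In 1 of the 10 splits of the libraries, the real one, camera's p was as small (6.06e-10, smallest other 3.2e-06), and 10 splits are too few for a share under 0.05. Camera's p for the list in the other splits ran from 3.2e-06 to 0.924. Some of these were small, such as 1.16e-04 and 4.35e-04, so a small camera p also arises without the label.

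Yy2 was nearly absent from the libraries labelled shDNAJB1. A C57BL/6 substrain difference that involves Nnt is argued against by a log2 difference of 0.0537 for that gene. The counts are uncertain, since 100% of the exonic bases of Yy2 lie in exons of Mbtps2 on the same strand, but this holds for all 6 libraries alike and the cause of the difference between groups remains open. Mbtps2 itself was at 0.00 (SE 0.11).

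For the mixed-direction calls of p53 and glucocorticoid targets, glucocorticoid exposure and p53 activity both stay open. The mean of Fkbp5, Sgk1, Tsc22d3 and Per1 was -0.0328 and the p53 list median was 0.00195, but members went both ways. The mean of the 12 glucocorticoid targets was 0.32 but their median was 0.12, and the largest member, Lcn2, was at 2.09. Their list score, which includes Lcn2, was higher in every library labelled shDNAJB1 (lowest 0.13) than in every control (highest -0.06). Chance alone separates the groups in 10% of cases, and the scores of the oligodendrocyte and other DnaJ lists were separate as well. The separation therefore does not single out the glucocorticoid list. Of the 10 splits, 1 had a p53 mixed p as small (1.16e-04, smallest other 0.0558). For genes past the threshold the real count was 0, which 10 of the 10 splits reach by construction, so this says nothing about chance, and the highest other was 2. For unadjusted genes it was 3 of 10 (real 1202, highest other 1717), for lists 10 of 10 (real 6, highest other 18), and for DESeq2 6 of 10 (real 24, highest other 106). The splits are too few for a share under 0.05. They do show that groupings other than the real one exceeded the real counts of unadjusted genes, lists and DESeq2 genes. Those counts alone thus give no evidence of an effect of the label. The DESeq2 split with 106 genes set control 1, shDNAJB1 2 and shDNAJB1 3 against the others and held several times the real count, which may come from a structure of the samples, but no test addressed one and edgeR called 0 genes in that split.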
